A study of Mus musculus with 68 samples.

How the data were processed

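Total RNA from 68 mouse samples, all labelled as prostate tumours, was hybridised by the authors to Clariom S arrays after biotin labelling. Per the labels' protocols, RNA was extracted with Qiazol and purified on RNeasy columns. The deposited table holds 1 log2 expression value per probe set and array. Per the submitters' processing notes these log2 values were made with RMA (background correction, quantile normalization and summarisation of probes) in the oligo package, and their versions are not given in the sources used here. The deposited values ran from 2.70 to 13.74, and array medians from 6.25 to 6.34. The matching of columns to samples used the sample identifiers in the table's header, and 0 columns were left unused. Values made by RMA compress large differences at low signal, and quantile normalization assumes that most probe sets do not move in one direction.

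The table has 29129 probe sets, of which 6923 are controls and stayed out of the tests, so that 22206 probe sets were tested with no filter on signal. The platform's annotation table gave 1 gene symbol for 19572 of them, none for 2634 and several for 0. All 19572 Entrez identifiers were matched to a RefSeq gene table of assembly GRCm38.p6, which altered 0 symbols. The platform's genome build is not given in the sources used here, so the gene table served for names only and no coordinates are printed. The symbols stand for 19505 genes. For 55 genes with more than 1 probe set the probe set with the highest mean over the arrays was used where a gene is named. No named probe set exists for Spp1, the gene of osteopontin (OPN), so the OPN genotype labels could not be checked on these arrays.

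Samples were placed in 12 groups by genotype and age in the labels. Each array comes from an animal with its own identification code, and arrays are called by these codes (T, TRAMP; ST, SPARC-null TRAMP; OT, OPN-null TRAMP; B, non-transgenic wild type; S, SPARC-null and O, OPN-null without the transgene). Array O12 carries a SPARC-null genotype label and a code of the OPN-null series, so it was kept out of the fits, which left 67 arrays. The groups, the 18 comparisons, the gene lists and the naming rule were fixed before the data were examined. The settings described with array quality, and the tests and genes named as such in the closing section, were chosen afterwards.

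Comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided moderated test, 1 mean per group) in 3 fits: the 38 transgenic arrays, the 29 non-transgenic arrays, and all 67 arrays with a weight per transgene status from arrayWeights (1.11 for transgenic and 0.87 for non-transgenic arrays). P-values were adjusted by the Benjamini-Hochberg method over the 22206 probe sets of each comparison, and probe sets with an adjusted p under 0.05 were called. Differences are on the log2 scale, with the standard error of the fit. The 18 comparisons were also run on simulated data in which 200 probe sets were shifted on the real arrays' spread. For the late OPN comparison 27% of shifts of log2 0.5 and 85% of shifts of log2 1 were recovered, with 3 false calls among 115. For the late SPARC comparison the shares were 56% and 93%, with 1 false call among 150. The simulated noise was drawn independently for each probe set, while probe sets on the real arrays vary together. These shares and false calls therefore may not hold for the real data. The number of arrays limits the precision of every difference.

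Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 26 lists of a comparison, and beside it with a correlation estimated per list and with fry, which asks whether a list's genes move on balance one way. The lists were: Neuroendocrine, Androgen-regulated and luminal secretory, Basal epithelium, Epithelial adhesion, Mesenchymal transition, Fibrillar collagen and matrix, Basement membrane, Matricellular proteins, Fibroblasts, Smooth muscle, Endothelium, Cell cycle, Mast cells, T and NK cells, B and plasma cells, Macrophages, Neutrophils, Interferon response, TNF and NF-kB response, Unfolded protein response, Hypoxia and glycolysis, Seminal vesicle, Skeletal muscle, Adipose tissue, Urothelium, and Autonomic neurons and glia. A list score per array is the mean of its members' log2 values, each centred on its mean over the arrays. Scores and their spread were compared by 2-sided exact permutation tests over all splits of the arrays, adjusted over 312 and 234 tests. The correlation of the first principal component with array quality was tested with 100000 random permutations. Sparc and the SV40 control probe sets were compared by 2-sided exact permutation tests.

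Named genes followed a fixed rule. Sparc and Spp1, where measured, were named in every comparison. The 8 largest called rises and falls with 1 symbol were named for the knockout and transgene comparisons in TRAMP and for age in TRAMP and SPARC-null TRAMP, and the 3 largest each way elsewhere. Predicted genes, olfactory and vomeronasal receptors, small RNAs and immune receptor segments were skipped. Up to 4 called members of each called list were named, or 2 members as values where none was called. A comparison without calls names the 3 smallest p-values each way as values only.

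Array quality was measured as the area under the ROC curve (AUC) that separates 1324 positive from 5222 negative control probe sets. After this measure had been seen, 2 settings were added: array quality as a covariate, and leaving out arrays with an AUC below 0.7. The list tests were also repeated under each setting, a step added at the same stage. Other settings tried were the brighter 60% of probe sets, equal array medians, quantile normalization within a fit, eBayes with trend and robust fitting, 1 weight per array, a fit on the compared groups alone, leaving out each array, probe sets with 1 symbol, age as a covariate, mice of 24 weeks alone, the identification number as a block, array O12 included, no weights, the probe set with the largest variance, and other forms of the list tests and scores. For each comparison up to 100 random regroupings of the arrays were refitted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.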

Results

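Gene expression was measured on 68 arrays of mouse samples labelled as prostate tumours. TRAMP mice, which carry the SV40 T antigens under the rat probasin promoter and develop prostate cancer, were set against TRAMP mice lacking SPARC, a collagen-binding matricellular protein, or OPN (osteopontin), a secreted matrix phosphoprotein. Non-transgenic mice of the same 3 genotypes were also profiled, and their samples carry the same tissue label although they lack the transgene. The early TRAMP group held 7 animals of 16 weeks, the early SPARC-null TRAMP group 6 of 18 to 19 weeks and the early OPN-null TRAMP group 6 of 16 to 17 weeks. The late groups held 7 TRAMP animals of 24 to 25 weeks, 9 SPARC-null TRAMP animals of 24 to 29 weeks and 3 OPN-null TRAMP animals of 24 to 27 weeks. Without the transgene there were 4 early and 6 late wild-type animals, 7 early and 4 late SPARC-null animals, and 5 early and 3 late OPN-null animals. The wild-type mice without the transgene were 16 and 24 weeks old and the OPN-null ones 16 to 17 and 24, while the SPARC-null ones were 16 to 18 and 25 to 27. The series speaks of adenocarcinoma and neuroendocrine carcinoma, but the sample labels give no tumour type, and arrays were never divided by it. Whether seminal vesicle and muscle were dissected away is not given in the sources used here, and Seminal vesicle scores of single arrays ran from -2.15 to 3.98 within late TRAMP and from -1.97 to 4.66 within early TRAMP.

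Positive and negative control probe sets were separated with an AUC of 0.674 to 0.799 per array. The first principal component held 33.9% of the variance over 67 arrays and followed this measure (Pearson r = 0.927, Spearman rho = 0.918, permutation p = 1e-05 for each, the smallest that the permutations can give). The relation kept r = 0.912 without the 2 arrays farthest from the median AUC, and r within the 7 groups of at least 6 arrays ran from 0.838 to 0.991. The late OPN-null TRAMP arrays had a mean AUC of 0.708 ± 0.0216 (SD, n = 3) against 0.731 ± 0.0187 (SD, n = 7) in late TRAMP. The lowest of these OPN-null arrays had 0.683, below the 0.7 used to leave out arrays of low quality. The highest correlation between any pair of arrays was 0.988, and 0 pairs held identical values. The negative control probe sets had a median of 5.37 and a 95th percentile of 9.25, so they set no clear background level, and a log2 difference from a value among them is not an exact size of change.

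Sparc, the gene deleted in the SPARC-null mice, was measured by 1 probe set (TC1100002783.mm.2). It averaged 6.25 ± 0.27 log2 units on the 26 SPARC-null arrays in the fits and 6.77 ± 0.35 on the other 41 arrays (SD), and 17 SPARC-null arrays lay above the lowest other array at 6.18. Without the transgene the SPARC-null groups were lower by exact permutation test, with a difference of -0.85 late (p = 0.00952, adjusted p = 0.0167) and -0.74 early (p = 0.00303, adjusted p = 0.0121). In TRAMP mice the difference was -0.34 late (exact p = 0.0125, adjusted p = 0.0167) and -0.25 early (exact p = 0.177). The SPARC-null values were not compared with background. The part of the transcript it measures and the deleted part are not given in the sources used here, so it checks the labels only in part. In the genome-wide limma tests Sparc differed by -0.34 (adjusted p = 0.999) in late and -0.25 (adjusted p = 0.706) in early SPARC-null TRAMP against TRAMP, and by 0.23 (adjusted p = 0.375) and -0.19 (adjusted p = 0.808) in the OPN-null groups. Between ages Sparc differed by -0.16 (adjusted p = 0.927) in TRAMP, -0.26 (adjusted p = 0.257) in SPARC-null TRAMP, 0.26 (adjusted p = 0.320) in OPN-null TRAMP and -0.06 (adjusted p = 0.998) in non-transgenic prostate. TRAMP differed from non-transgenic prostate in Sparc by -0.21 early (adjusted p = 0.818) and -0.32 late (adjusted p = 0.615), and the OPN-null from the wild-type non-transgenic mice by 0.04 (adjusted p = 0.916). Array O12, labelled SPARC-null, had 7.24.

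Control probe sets named for the SV40 genome, 6 in number, averaged 7.22 ± 0.55 on the 38 transgenic arrays and 5.22 ± 0.15 on the 30 non-transgenic arrays (SD). The lowest transgenic array, at 5.855, lay above the highest non-transgenic array, at 5.52. The late group exceeded the early group by 0.75 within SPARC-null TRAMP (exact permutation p = 0.0038, adjusted p = 0.0266), by 0.48 within TRAMP (p = 0.0519, adjusted p = 0.121) and by 0.70 within OPN-null TRAMP (p = 0.0952, adjusted p = 0.133). Late OPN-null TRAMP exceeded late TRAMP by 0.59 (exact permutation p = 0.0333, adjusted p = 0.117). The part of the SV40 genome that these probe sets match is not given in the sources used here.

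**Figure D1:**
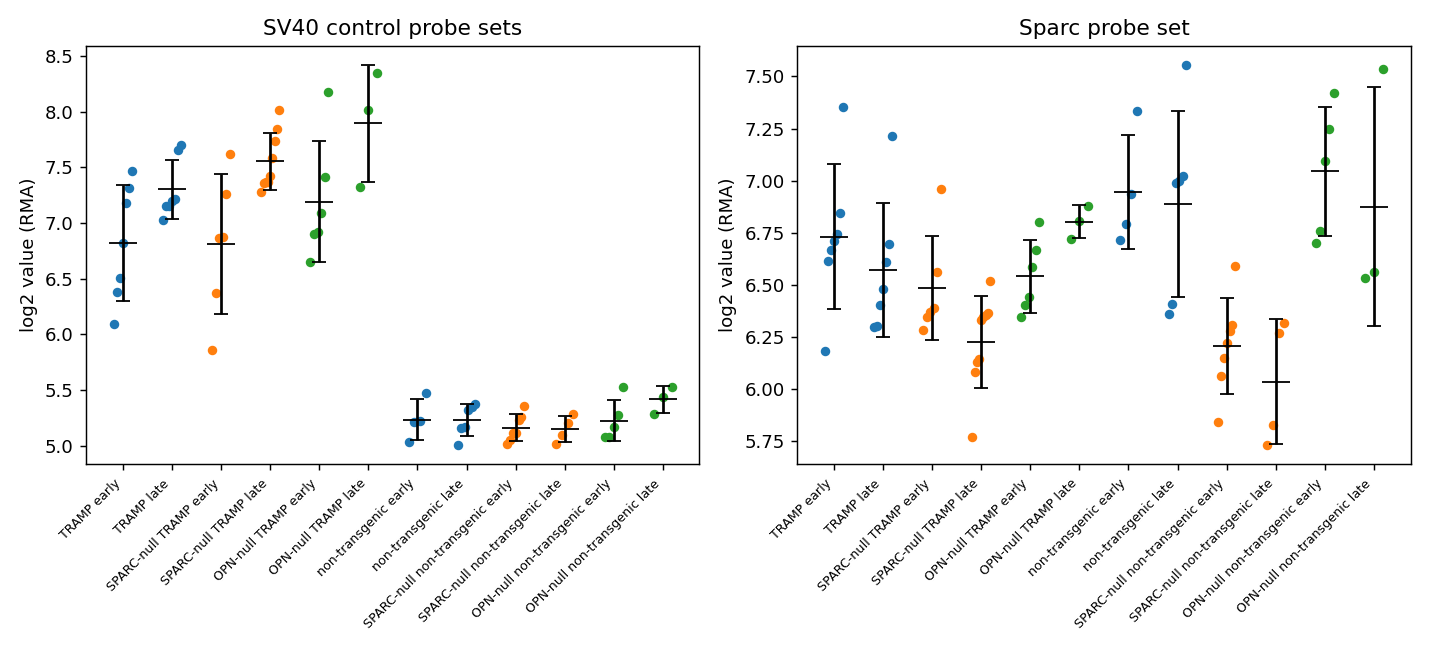
Mean log2 signal of the SV40 control probe sets (left) and log2 value of Sparc (right) for each of 67 arrays, by genotype and age group; points are arrays sorted by value within a group, and bars give the group mean and SD. All 38 transgenic arrays lie above the highest non-transgenic array in SV40 signal, while Sparc overlaps between SPARC-null arrays and the others.

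Late OPN-null TRAMP tumours were compared with late TRAMP tumours. Neuroendocrine genes rose and luminal secretory, epithelial adhesion and smooth muscle genes fell in the 3 OPN-null tumours. Among the largest rises, Slc25a21, a mitochondrial carrier of oxodicarboxylates (TC1200001797.mm.2), went from 4.11 ± 0.74 (SD, n = 7) to 9.38 ± 0.56 (SD, n = 3), a log2 difference of 5.27 (SE 0.27, adjusted p = 2.19e-17). The neuronal RNA-binding proteins Elavl4 and Elavl3 rose by 4.33 and 3.995, the synaptic vesicle calcium sensor Syt1 by 4.04, and the ephrin receptor Epha7 by 3.36. The non-coding RNA Ipw rose by 4.79, the matricellular gene Ccn3 by 4.30 and the protocadherin Pcdh8 by 3.09. Pbsn, which encodes the androgen-regulated secretory protein probasin (TC0X00002507.mm.2), fell from 10.33 ± 1.51 (SD, n = 7) to 4.95 ± 0.62 (SD, n = 3), a log2 difference of -5.39 (SE 0.63, adjusted p = 3.13e-08). The lower values lay within the range of the negative control probe sets, with 27.8% of these below Slc25a21 in TRAMP and 42.8% below Pbsn in OPN-null tumours, so no fold changes are given. Other large falls were those of the tetraspanin Tspan1 at -4.88, Pate9 at -4.80, the polymeric immunoglobulin receptor Pigr at -4.75, Zfp992 at -4.61 and Plac8 at -4.59. For each gene named so far, all 3 OPN-null tumours lay outside the range of the 7 TRAMP tumours. The unnamed probe sets with the smallest p rose by 3.36 and 3.10.

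By list, 12 of 22 measured Neuroendocrine genes rose and 0 fell (13 higher and 1 lower adjusted over the list alone; camera adjusted p = 1.51e-10). Snap25 of the synaptic fusion machinery rose by 2.29, the monoamine enzyme Ddc by 1.90, synaptophysin (Syp) by 1.68 and the neuroendocrine transcription factor Insm1 by 1.41. The list's members Foxa2 and Sox2 were not called, and their differences, both negative, are given in the closing section. Of the Androgen-regulated and luminal secretory list, 13 of 23 genes fell and 0 rose (14 lower adjusted over the list alone; adjusted p = 3.17e-09). Beside Pbsn, the falls were -4.43 for the beta-defensin Defb50, -4.26 for the prostate transglutaminase Tgm4 and -4.10 for Wfdc15b. Epithelial adhesion genes fell in 7 of 13 cases (11 adjusted over the list alone; adjusted p = 4.76e-09), with -2.01 for the epithelial transcription factor Grhl2, -1.81 for both Epcam and E-cadherin (Cdh1) and -1.62 for the claudin Cldn7. Smooth muscle genes fell in 11 of 12 cases (12 adjusted over the list alone; adjusted p = 1.17e-14), among them the contractile genes Actg2 at -4.64, Synpo2 at -4.21, Acta2 at -4.04 and Cnn1 at -3.20. These 4 lists were also called with an estimated correlation (adjusted p = 0.0151 for Neuroendocrine and 0.0204 for each of the others).

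The remaining 7 called lists of late OPN-null TRAMP lost their call with an estimated correlation. Cell cycle genes rose in 12 of 24 cases (14 adjusted over the list alone; adjusted p = 2.39e-07, and 0.0699 with an estimated correlation), with Ezh2 at 1.38, Bub1 at 1.26, Pcna at 1.15 and Ccne2 at 1.10. Unfolded protein response genes fell in 11 of 16 cases (12 adjusted over the list alone; adjusted p = 3.41e-07, and 0.146 with an estimated correlation), with the chaperone genes Dnajc3 at -2.26, Pdia6 at -1.52 and Hspa5 at -1.48 and Herpud1 at -1.48. Interferon response genes fell in 7 of 15 cases (7 adjusted over the list alone; adjusted p = 0.00154, and 0.0699 with an estimated correlation), with Bst2 at -1.70, Gbp3 at -1.42, Usp18 at -1.01 and Ifit2 at -0.79. Urothelium markers fell in 4 of 8 cases (4 adjusted over the list alone; adjusted p = 0.0112, and 0.0939 with an estimated correlation), led by the uroplakins Upk1b at -3.83 and Upk1a at -1.33. Basement membrane genes fell in 5 of 16 cases (7 adjusted over the list alone; adjusted p = 0.0155, and 0.138 with an estimated correlation), with the laminin subunits Lamc1 at -1.81, Lamb2 at -1.04 and Lama2 at -0.87. Macrophage genes fell in 4 of 13 cases (4 adjusted over the list alone; adjusted p = 0.0155, and 0.194 with an estimated correlation), with C1qa at -0.89 and Lyz2 at -0.68. Adipose tissue genes fell in 2 of 9 cases (4 adjusted over the list alone; adjusted p = 0.0155, and 0.299 with an estimated correlation), namely Lep at -0.84 and Plin4 at -0.54. The call of Basement membrane was lost without OT3 (0.054) or OT6 (0.0613) and without arrays of low quality (0.0684), that of Macrophages without OT2 (0.0916) and that of Adipose tissue without OT6 (0.0586).

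The other 15 lists were not called in late OPN-null TRAMP. Among the lists of cell types and matrix, 1 of 11 Basal epithelium genes rose and 1 fell, 0 of 19 Fibrillar collagen and matrix genes rose and 4 fell (adjusted p = 0.0577), and 1 of 13 Fibroblasts genes rose and 4 fell. For the 14 Matricellular proteins, 3 rose and 2 fell, and for the 10 Endothelium genes 1 rose and 3 fell. Mesenchymal transition genes rose in 2 and fell in 6 of 15 cases (adjusted p = 0.0577). Immune lists gave 1 fall among 14 Mast cells genes, 2 rises and 1 fall among 16 T and NK cells genes, 1 rise among 11 B and plasma cells genes and 2 rises among 11 Neutrophils genes. The TNF and NF-kB response list had 3 falls among 17 genes (adjusted p = 0.0568), the Hypoxia and glycolysis list 1 rise and 1 fall among 16, the Seminal vesicle list 0 called genes among 10, and the Skeletal muscle list 1 fall among 11. The Autonomic neurons and glia list had 2 rises and 1 fall among 9 genes (mean difference 0.0405, adjusted p = 0.906).

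In total 4777 probe sets were called in late OPN-null TRAMP, 2475 higher and 2302 lower, and 1023 of them by at least 2-fold, with 7590 at an unadjusted p under 0.05 where 1110 are due by chance. The ranges of the groups did not overlap for 3207 of the called probe sets, and 17.9% of all probe sets had ranges apart where chance gives 1.67%. Score differences were 0.77 for Neuroendocrine, -1.54 for luminal secretory and -2.33 for Smooth muscle, each with exact permutation p = 0.00833, the smallest that the 120 splits of 3 against 7 animals allow (adjusted p = 0.0743). Over all 312 score tests 0 passed the adjustment, and of 234 tests of the spread of scores between groups 0 passed, with 31 at an unadjusted permutation p under 0.05. With age in weeks as a covariate the count was 2986. It was 4211 without arrays of low quality, a setting that also drops the OPN-null tumour with the lowest AUC (0.683).

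**Figure D2:**
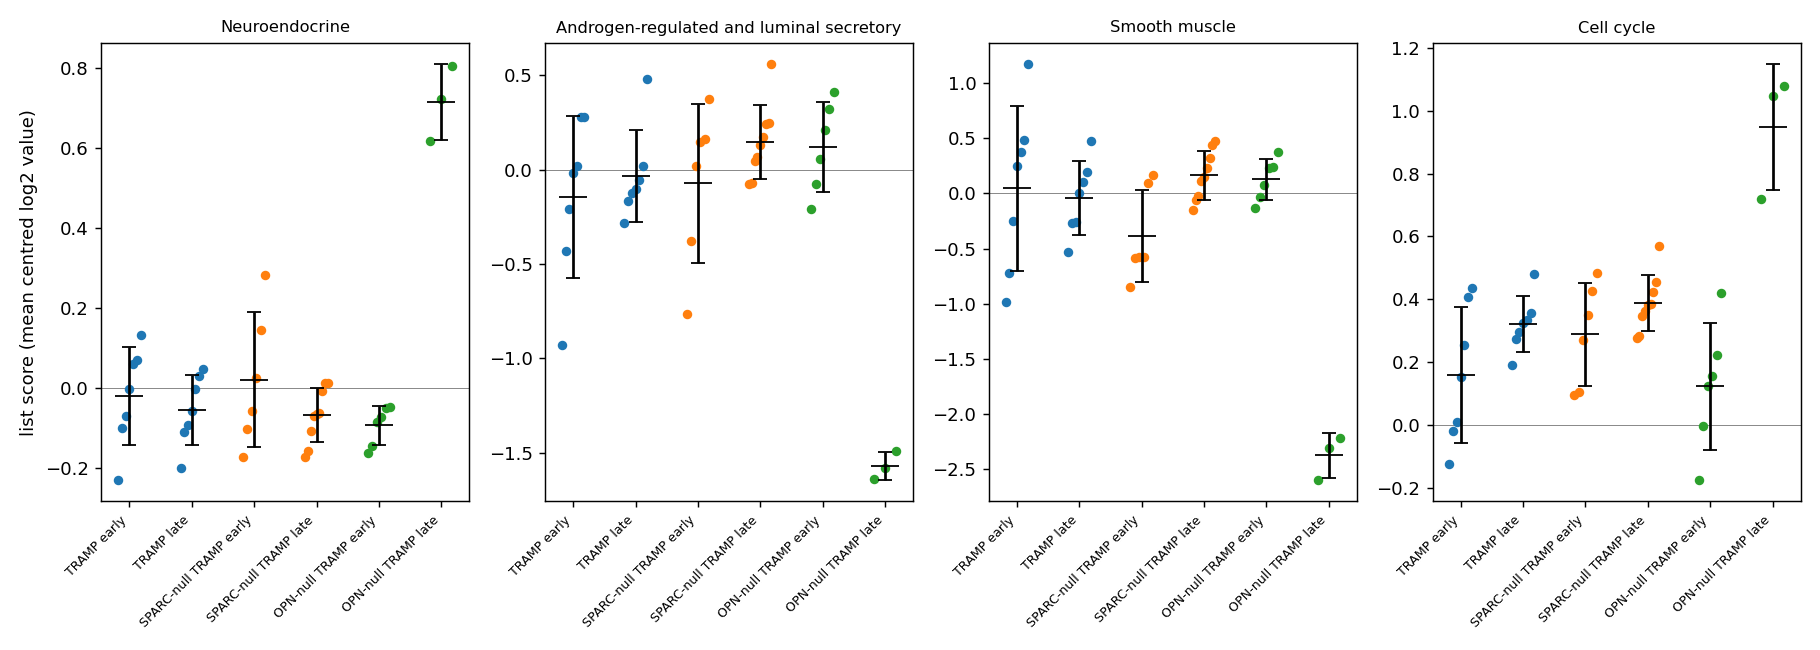
List scores (mean centred log2 value of the list's members) per array for the Neuroendocrine, luminal secretory, Smooth muscle and Cell cycle lists in the 6 transgenic groups; points are arrays sorted by value within a group, and bars give the group mean and SD. The 3 late OPN-null TRAMP arrays stand apart from the 7 late TRAMP arrays in all 4 scores, with a mean difference of 0.77 for Neuroendocrine and -2.33 for Smooth muscle.

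Early OPN-null TRAMP tumours of 16 to 17 weeks were set against early TRAMP tumours. The chaperone gene Hsph1 rose by 1.04 (SE 0.18, adjusted p = 0.0256), from 6.93 ± 0.37 (SD, n = 7) to 7.97 ± 0.28 (SD, n = 6), and was the only call. The Unfolded protein response list was called higher with 0 of 16 genes called and 11 adjusted over the list alone (adjusted p = 1.04e-11, and 0.3 with an estimated correlation). Its largest differences were 1.22 (SE 0.55) for Dnajb9 and 1.13 (SE 0.33) for Creld2. The lowest Unfolded protein response scores of early TRAMP were those of T10 (-1.10), T9 (-0.57) and T8 (-0.48), the 3 arrays of the group with the lowest AUC (0.674, 0.707 and 0.706), while the other 4 ran from -0.15 to 0.53 and the OPN-null arrays, with an AUC of at least 0.723, from 0.09 to 0.64. The list kept its call with array quality as a covariate (adjusted p = 2.64e-08) and without arrays of low quality (5.43e-08). The Androgen-regulated and luminal secretory list (adjusted p = 0.000986) and the Epithelial adhesion list (adjusted p = 0.00327) were called higher with 0 genes called, each with an adjusted p of 0.629 with an estimated correlation, 0.213 with array quality as a covariate, 0.105 without arrays of low quality and 0.113 without T10. Pbsn differed by 0.96 (SE 0.50), Tgm4 by 0.86 (SE 0.48), Epcam by 0.52 (SE 0.29) and Tjp1 by 0.34 (SE 0.20). At an unadjusted p under 0.05 there were 1450 probe sets. Without any 1 of T8, T9, T10, T12, T14, OT9, OT11, OT12, OT13 or OT14 the count was 0, as it was with 1 weight per array, in a fit on the compared groups alone and without arrays of low quality.

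The effect of OPN loss was tested for a difference between the ages. Slc25a21 rose more in late than in early tumours by 5.22 (SE 0.34), Ipw by 4.44 and Elavl4 by 4.30, and the difference was negative for the seminal vesicle gene Svs5 at -7.96 (SE 2.46), Pbsn at -6.35 (SE 0.80) and Pigr at -5.74. Carried-over seminal vesicle tissue was not separated from the OPN effect for Svs5. The sizes for Slc25a21 and Pbsn are not exact, since Slc25a21 lay among the negative controls in both TRAMP groups and early OPN-null tumours (25.3% to 27.8% of them below it) and Pbsn in late OPN-null tumours (42.8%). Neuroendocrine genes were more positive late in 12 of 22 cases and more negative in 1 (the same adjusted over the list alone; adjusted p = 3e-10), among them Snap25 at 2.22, Ddc at 2.10, Syp at 1.69 and Chgb at 1.51. More negative late were 13 of 23 luminal secretory genes (14 adjusted over the list alone; adjusted p = 8.93e-11), with Tgm4 at -5.12, Defb50 at -4.88 and Wfdc15b at -4.16, 10 of 13 Epithelial adhesion genes (10 alone; adjusted p = 2.22e-10), with Epcam at -2.33 and Cdh1 at -2.14, and 9 of 12 Smooth muscle genes (9 alone; adjusted p = 4.15e-13), with Actg2 at -4.87 and Acta2 at -4.45. These 4 lists kept their calls with an estimated correlation (adjusted p = 0.0134, and 0.0306 for Smooth muscle). Calls lost with an estimated correlation were those of Unfolded protein response (11 of 16 more negative; adjusted p = 0.0861), Interferon response (4 of 15 more negative; 0.0972), Cell cycle (11 of 24 more positive; 0.113), Urothelium (1 of 8 more negative; 0.118), Mesenchymal transition (4 of 15 more negative and 2 more positive; 0.173), Macrophages (2 of 13 more negative; 0.29) and Adipose tissue (1 of 9 more negative; 0.348). Examples were Dnajc3 at -3.30, Bst2 at -1.84 and Ezh2 at 1.60. Mesenchymal transition also lost its call with array quality as a covariate (0.18) and without T10 (0.0509), OT2 (0.149) or OT6 (0.0579). The same held for Macrophages without OT2 (0.121) or OT6 (0.0522), and for Adipose tissue with the covariate (0.0596), without arrays of low quality (0.0692) and without OT6 (0.059). Sparc differed by 0.42 (adjusted p = 0.210). In total 3539 probe sets differed between the ages in their OPN effect, 1926 higher and 1613 lower, or 2235 with age in weeks as a covariate.

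Age itself was compared within each transgenic genotype. In OPN-null TRAMP, Slc25a21 rose by 5.39 (SE 0.28) from early to late, Ipw by 4.56 and Ccn3 by 4.47, while Svs5 fell by 7.11 (SE 1.96), Pbsn by 6.21 (SE 0.64) and Pate14 by 5.93 (SE 1.47). Early Slc25a21 and late Pbsn lay among the negative controls (25.7% and 42.8% of them below), so these 2 sizes are not exact. Cell cycle genes rose in 16 of 24 cases (20 adjusted over the list alone; adjusted p = 4.85e-10, and 0.0272 with an estimated correlation), with Pcna at 1.73, Ccne2 at 1.54, Cdk1 at 1.495 and Ezh2 at 1.46. Neuroendocrine genes rose in 12 and fell in 1 of 22 cases (16 and 1 adjusted over the list alone), luminal secretory genes fell in 12 of 23 (14 alone), Epithelial adhesion genes in 10 of 13 (12 alone) and Smooth muscle genes in 12 of 12, and each of these lists had an adjusted p of 0.0113 with an estimated correlation. Urothelium genes fell in 4 of 8 cases (adjusted p = 0.0461 with an estimated correlation). Lists called lower whose calls were lost with an estimated correlation were Unfolded protein response (12 of 16 lower; adjusted p = 0.0644), Fibroblasts (5 of 13 lower, 1 higher; 0.0714), Basement membrane (6 of 16 lower; 0.0949), Mesenchymal transition (5 of 15 lower, 2 higher; 0.173), Interferon response (2 of 15 lower; 0.173), Macrophages (3 of 13 lower; 0.317), Adipose tissue (2 of 9 lower; 0.317), Skeletal muscle (3 of 11 lower; 0.379) and Seminal vesicle (3 of 10 lower; 0.463). Called falls among them included Dpt at -1.29, Creld2 at -2.17, Fabp4 at -3.17 and Myh1 at -2.81. With array quality as a covariate the adjusted p was 0.193 for Mesenchymal transition, 0.0722 for Fibroblasts and 0.164 for Seminal vesicle, and without arrays of low quality 0.0505 for Interferon response. Without OT2 the calls of Mesenchymal transition (0.203), Fibroblasts (0.0543) and Macrophages (0.161) were lost, without OT6 the same 3 (0.0531, 0.0884 and 0.0531), without OT3 that of Interferon response (0.0556) and without OT8 that of Fibroblasts (0.0518). In total 4969 probe sets were called, 2839 higher and 2130 lower. With age in weeks as a covariate, which nearly repeats the contrast, 340 were called.

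In TRAMP mice with SPARC and OPN, 0 probe sets were called by limma between the ages, with 1063 at an unadjusted p under 0.05. The smallest p-values were those of Klhl18 (0.38), Sel1l3 (0.62) and Pot1b (0.57) among positive differences, and of Myl2 (-0.51), Ercc3 (-0.46) and the matrix proteoglycan gene Prelp (-0.39) among negative ones. The Cell cycle list (adjusted p = 0.0033) and the Interferon response list (adjusted p = 0.00599) were called higher with age and the Skeletal muscle list lower (adjusted p = 0.0033), with 0 genes called in each, and with an estimated correlation their adjusted p was 0.649, 0.479 and 0.684. The Cell cycle call was lost without T13 (0.097) or T14 (0.0808), and the Skeletal muscle call without T2 (0.0525), T7 (0.0734) or T12 (0.0691). Ccne2 differed by 0.59, Mki67 by 0.45, Gbp3 by 0.54, Irf7 by 0.40, Myh4 by -1.48 and Myh8 by -1.27. Adding age in weeks as a covariate gave 337 calls.

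SPARC-null TRAMP mice also gave 0 calls between the ages, with 4747 at an unadjusted p under 0.05. The smallest p-values were those of Egflam (0.52), Hepacam2 (0.90), Gng11 (0.51), Zfp865 (-0.44), coagulation factor gene F12 (-0.65) and Kynu (-0.50), with adjusted p from 0.0679 for Zfp865 to 0.102 for Gng11. Smooth muscle (adjusted p = 8.6e-05), Interferon response (0.00096), Unfolded protein response (0.00562), luminal secretory (0.00925), Epithelial adhesion (0.0154) and Mesenchymal transition (0.0154) lists were called higher, and Skeletal muscle lower (0.0237), with 0 genes called and at most 4 adjusted over the list alone, for Interferon response. Their adjusted p with an estimated correlation lay between 0.173 for Interferon response and 0.684 for Skeletal muscle. With array quality as a covariate the calls of the luminal secretory (0.235), Epithelial adhesion (0.174) and Unfolded protein response (0.161) lists were lost, as they were without arrays of low quality (0.0916, 0.101 and 0.0743) and without ST22 (0.0908, 0.104 and 0.0908). The early arrays ST22 and ST23, with the lowest AUC of the group (0.689 and 0.706), had the lowest Unfolded protein response scores, -1.14 and -0.51, while the other 4 ran from -0.25 to 0.14. Without ST26 the calls of Epithelial adhesion (0.0669) and Mesenchymal transition (0.0565) were lost, and the Skeletal muscle call without ST2 (0.0526), ST16 (0.0641), ST24 (0.0651), ST25 (0.145) or ST26 (0.075). The differences were 1.22 for Pcp4, 0.93 for Acta2, 1.08 for Gbp3, 0.90 for Cxcl9, 1.79 for Dnajb9 and -1.30 for Myh1. The count was 279 without array ST25, 266 without ST24 and 1 without ST6, and it was 2263 with age in weeks as a covariate.

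Late SPARC-null TRAMP tumours were compared with late TRAMP tumours, the comparison named by the series. Of the 9 SPARC-null animals 7 were 27 to 29 weeks old, against 24 to 25 weeks in TRAMP, so age largely goes with genotype. Both called probe sets have no gene symbol and were lower in SPARC-null tumours, TC0M00000009.mm.2 by -2.16 (SE 0.14, adjusted p = 6.29e-13) and TC0100001206.mm.2 by -3.52 (SE 0.57, adjusted p = 0.00397). Among named genes the smallest p-values were those of Dsel at 0.69 (SE 0.14, adjusted p = 0.0919), Tvp23b at 0.44 (SE 0.10) and the trefoil factor gene Tff3 at 1.52 (SE 0.35), and of Afg1l at -0.39, Lrit2 at -0.33 and Cd72 at -0.28, and none passed the test. Lists called higher were Androgen-regulated and luminal secretory (adjusted p = 0.000402), Epithelial adhesion (0.0055), Smooth muscle (0.0216), Unfolded protein response (0.0228), Mesenchymal transition (0.0356), Cell cycle (0.0356) and Interferon response (0.0431), each with 0 genes called. All were lost with an estimated correlation, where the smallest adjusted p was 0.467. All 7 were also lost with array quality as a covariate, with an adjusted p of 0.168 for luminal secretory, Cell cycle and Interferon response, 0.18 for Epithelial adhesion, 0.193 for Mesenchymal transition, 0.664 for Smooth muscle and 0.863 for Unfolded protein response, whose direction turned. Interferon response was lost without arrays of low quality (0.0636). Leaving out single arrays ended 5 of the 7 calls: Mesenchymal transition without T1 (0.0717), T2 (0.0658), T4 (0.131), T5 (0.069), ST1 (0.0583), ST3 (0.0531), ST4 (0.0519), ST6 (0.0542) or ST15 (0.0554), and Smooth muscle without T1 (0.0617), T4 (0.149), T7 (0.0506), ST7 (0.0525) or ST15 (0.0554). Cell cycle was lost without T3 (0.0718), T4 (0.0893), T5 (0.15), T6 (0.0604), ST4 (0.0884), ST7 (0.158) or ST15 (0.0554). Interferon response was lost without T1 (0.127), T2 (0.271), T4 (0.0542), T6 (0.0604), ST4 (0.0884), ST5 (0.213), ST6 (0.0739), ST7 (0.153) or ST15 (0.0554). Unfolded protein response was lost without T1 (0.0717), T2 (0.0658), T4 (0.131), T5 (0.0638), ST1 (0.0513), ST4 (0.0504) or ST15 (0.0554). Member differences were 0.82 (SE 0.53) for Msmb, 0.64 (SE 0.46) for Pbsn, 0.41 (SE 0.18) for Cdh1, 0.40 (SE 0.16) for Cldn4, 0.40 (SE 0.18) for Fn1, 0.29 (SE 0.14) for Top2a and 0.69 (SE 0.24) for Cxcl9. At an unadjusted p under 0.05 there were 719 probe sets where 1110 are due by chance. The count was 7 with 1 weight per array, 72 with age in weeks as a covariate and 206 among mice of 24 weeks, where 2 SPARC-null animals remained.

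Early SPARC-null TRAMP tumours, from animals of 18 to 19 weeks, were set against early TRAMP tumours of 16 weeks. The ages of the groups do not overlap, so an effect of age cannot be told apart from one of genotype. The basement membrane linker gene Nid1 fell by 0.59 (SE 0.11, adjusted p = 0.0437), from 7.38 ± 0.25 (SD, n = 7) to 6.80 ± 0.13 (SD, n = 6), and the zinc finger gene Zfp865 rose by 0.45 (SE 0.08, adjusted p = 0.0437). The unnamed probe sets TC0M00000009.mm.2 and TC0100001206.mm.2 fell by 2.19 and 3.31. The Smooth muscle list was called lower with 0 of 12 genes called and 1 adjusted over the list alone (adjusted p = 4.83e-06, and 0.411 with an estimated correlation), with Pcp4 at -0.90 (SE 0.32) and Des at -0.69 (SE 0.30). The Fibroblasts list was called lower with 0 of 13 genes called (adjusted p = 0.0401, and 0.0962 with an estimated correlation), with Pi16 at -0.43 and Clec3b at -0.41. Its call was lost with array quality as a covariate (0.0566) and without T9 (0.0732), T13 (0.0888), ST24 (0.153), ST25 (0.126) or ST26 (0.0836). There were 4 calls, 1 higher and 3 lower, and 1706 probe sets at an unadjusted p under 0.05. The share of calls that were higher was 25%, 50% with equal array medians and 40% with quantile normalization. The count was 2 without T8, T9 or T12 and 1 without T11, T13, T14, ST22, ST23, ST26 or ST27, and 29 with array quality as a covariate.

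For the difference between the ages in the SPARC effect, limma called 0 probe sets, with 858 at an unadjusted p under 0.05. Nid1 (0.59), Egflam (0.64) and Podn (0.70) had the smallest p-values among positive differences, and Zfp865 (-0.56), Arsi (-0.50) and Dnajc16 (-0.58) among negative ones. The Smooth muscle list was called higher (adjusted p = 6.25e-09, and 0.228 with an estimated correlation), with Pcp4 at 1.21 and Mylk at 1.03. The Fibroblasts list was called higher by camera (adjusted p = 0.0152, and 0.0431 with an estimated correlation) but not by fry (adjusted p = 0.166). The estimated correlation was -0.00386, close to the preset one, so the test with it adds little. In this list 0 of 13 genes were called, with Ly6c1 at 0.75 and Pi16 at 0.53. Its call was lost without T7 (0.0509), T9 (0.0528), ST24 (0.0857) or ST25 (0.0521). Sparc differed by -0.10.

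The knockouts were also compared with each other. Late SPARC-null TRAMP tumours exceeded late OPN-null TRAMP tumours by 6.03 (SE 0.60) in Pbsn, 5.31 in Pigr and 5.14 in Tspan1, and were lower in Slc25a21 by -5.48 (SE 0.26), Ipw by -5.17 and Ccn3 by -4.58. The lower values of Pbsn and Slc25a21 lay among the negative controls (42.8% and 24% of them below), so these 2 sizes are not exact. Sparc was lower by -0.58 (SE 0.17, adjusted p = 0.0106). Luminal secretory genes were higher in 14 of 23 cases (15 adjusted over the list alone), Epithelial adhesion genes in 11 of 13 (12 alone), Smooth muscle genes in 12 of 12 and Interferon response genes in 9 of 15 (9 alone), and Neuroendocrine genes were lower in 13 and higher in 1 of 22 (14 and 1 alone). These 5 lists held with an estimated correlation (adjusted p = 0.0159 for Neuroendocrine, luminal secretory and Epithelial adhesion, 0.0196 for Smooth muscle and 0.0356 for Interferon response). Bst2 was higher by 1.93, Cxcl9 by 1.25 and Cdh1 by 2.21, and Chgb was lower by -1.32. Calls lost with an estimated correlation were Urothelium (4 of 8 higher; adjusted p = 0.0582), Mesenchymal transition (9 of 15 higher, 2 lower; 0.113), Unfolded protein response (12 of 16 higher; 0.125), Cell cycle (12 of 24 lower; 0.127), Basement membrane (6 of 16 higher, 1 lower; 0.163), TNF and NF-kB response (4 of 17 higher; 0.163), Macrophages (5 of 13 higher; 0.204) and Adipose tissue (3 of 9 higher; 0.38). Within Mesenchymal transition, Fn1 was higher by 1.06 and N-cadherin (Cdh2) lower by -1.19, and in the TNF and NF-kB response list Nfkbia was higher by 0.55. With array quality as a covariate the calls of Mesenchymal transition (0.0749) and Adipose tissue (0.0655) were lost, and without arrays of low quality those of Basement membrane (0.107), TNF and NF-kB response (0.0537) and Adipose tissue (0.0552). Without OT2 the calls of Mesenchymal transition, Macrophages (0.0904 for each) and TNF and NF-kB response (0.098) were lost, without OT6 those of Basement membrane (0.101), TNF and NF-kB response and Adipose tissue (0.0784 for each) and without OT3 that of Basement membrane (0.0856). The TNF and NF-kB response call was also lost without ST1 (0.0524), ST4 (0.0608), ST5 (0.0589) or ST6 (0.0686). There were 6563 calls, 3052 higher and 3511 lower, and the comparison shares its 3 OPN-null arrays with the late OPN comparison.

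The early SPARC-null TRAMP animals were 18 to 19 weeks old and the early OPN-null TRAMP animals 16 to 17. Their ages do not overlap, so in this comparison an effect of age cannot be told apart from one of genotype. Early SPARC-null TRAMP tumours exceeded early OPN-null TRAMP tumours in the tRNA methyltransferase gene Trmo by 0.61 (SE 0.11, adjusted p = 0.0147) and in Zfp865 by 0.56 (SE 0.09, adjusted p = 0.00162), while Sparc differed by -0.06 (adjusted p = 0.891). TC0M00000009.mm.2 and TC0100001206.mm.2 were lower by -2.25 and -3.76, which made 4 calls, with 3090 probe sets at an unadjusted p under 0.05. The Unfolded protein response list (adjusted p = 5.28e-08, and 0.443 with an estimated correlation) and the Smooth muscle list (adjusted p = 1.45e-05, and 0.546 with an estimated correlation) were called lower with 0 genes called (6 and 1 adjusted over the list alone), with Dnajb9 at -2.06, Dnajc3 at -1.17, Pcp4 at -1.18 and Mylk at -1.01. The lowest Unfolded protein response scores were those of the SPARC-null arrays ST22 (-1.14) and ST23 (-0.51), with an AUC of 0.689 and 0.706, while the other 4 SPARC-null arrays ran from -0.25 to 0.14. The AUC averaged 0.724 in early SPARC-null and 0.739 in early OPN-null tumours. Both lists kept their calls with array quality as a covariate (adjusted p = 2.51e-06 and 0.00157), without arrays of low quality (1.16e-05 and 9.74e-05) and without any 1 array. The count was 62 without array ST25, 7 without OT12 and 2 without OT14, and it was 1 with age in weeks as a covariate.

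The transgene was tested by comparing TRAMP with wild-type non-transgenic prostate. At 16 weeks the chromatin remodeller gene Hells rose by 2.498 (SE 0.31, adjusted p = 1.26e-06), from 5.82 ± 0.72 (SD, n = 4) to 8.32 ± 0.78 (SD, n = 7), a size that is not exact because 57% of the negative controls lay below the lower value. Cyclin E2 (Ccne2) rose by 2.03, the proliferation marker Mki67 by 1.35, Ube2c by 1.32, the replication licensing gene Cdc6 by 0.93 and Casp2 by 0.71, and Gpcpd1 fell by 1.21. The Cell cycle list rose with 2 of 24 genes called and 15 adjusted over the list alone (adjusted p = 5.51e-22, and 6.7e-05 with an estimated correlation). The luminal secretory list (Spink1 at -3.19 and Sbp at -2.85) and the Seminal vesicle list (Pate4 at -4.17 and Svs5 at -3.49) were called lower with 0 genes called, and 3 luminal genes adjusted over the list alone (adjusted p = 0.00302 for each, and 0.513 and 0.659 with an estimated correlation). With array quality as a covariate both calls were lost (0.821 and 0.151), and the luminal call also without arrays of low quality (0.153), T10 (0.079) or B8 (0.0562). Without B11 the Seminal vesicle call was lost (0.343). There were 8 calls, 7 higher and 1 lower. The count was 45 without array T13, 5 without T9 or B13, 4 without T8, B8, B10 or B11 and 3 without T11, and it was 150 with 1 weight per array and 60 without arrays of low quality.

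At 24 to 25 weeks Hells was higher in TRAMP by 2.96 (SE 0.28, adjusted p = 2.77e-11), at 8.65 ± 0.27 (SD, n = 7) against 5.69 ± 0.22 (SD, n = 6), where 55.8% of the negative controls lay below the lower value, so the size is not exact. The mitotic kinase gene Pbk rose by 2.67, Ccne2 by 2.57, the histone chaperone Asf1b by 2.30, the tubulin regulator Stmn1 by 2.15, the condensin subunits Smc4 and Ncapg2 by 1.89 and 1.81, and Ube2c by 1.77. The falls were smaller, with Pi15 at -0.68, the securin gene Pttg1 at -0.56 and Myo3b at -0.44. Cell cycle genes rose in 13 of 24 cases (18 adjusted over the list alone; adjusted p = 1.47e-35, and 3.17e-07 with an estimated correlation), with Pcna at 1.73, Mki67 at 1.67 and Mcm4 at 1.17. Interferon response genes rose in 2 of 15 cases (5 adjusted over the list alone; adjusted p = 8.47e-06, and 0.00493 with an estimated correlation), namely Usp18 at 0.88 and Irf7 at 0.71. The group means of Irf7 (4.815 against 4.108) and of Mcm4 (5.296 against 4.124) lay below the negative control median of 5.37, so these sizes are not exact. The Epithelial adhesion list was called higher with 0 genes called and 2 adjusted over the list alone (adjusted p = 0.0414, and 0.763 with an estimated correlation), with Grhl2 at 0.84 (SE 0.23) and Epcam at 0.42 (SE 0.28). This call was lost without arrays of low quality (0.627) and without B6 (0.642), T3 (0.128), T6 (0.0554), T7 (0.0612) or B2 (0.0519), and it was kept with array quality as a covariate (0.00621). The score of B6 was -0.80, and those of the other 5 non-transgenic arrays ran from -0.08 to 0.18. There were 140 calls, 136 higher and 4 lower. The count was 89 without array T7, 68 in a fit on the compared groups alone, 789 with 1 weight per array and 378 with array quality as a covariate, where 84.7% were higher against 97.1%.

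In non-transgenic prostate, SPARC loss was tested over both ages, with late SPARC-null mice of 25 to 27 weeks against wild-type mice of 24 and early ones of up to 18 weeks against 16, so that age goes with genotype. Sparc fell by 0.80 (SE 0.15, adjusted p = 0.0287), the proteoglycan gene Fmod (fibromodulin) by 0.66 (SE 0.12) and Pttg1 by 0.87 (SE 0.11). The strain background of the SPARC-null line was not separated from SPARC loss for Fmod, Pttg1 or any other gene. The glycine cleavage gene Amt rose by 0.93 (SE 0.19), the sterol synthesis gene Msmo1 by 0.89 (SE 0.15) and the nicotinic receptor subunit Chrna3 by 0.89 (SE 0.18). TC0100001206.mm.2 and TC0M00000009.mm.2 fell by 4.11 and 2.29. The Unfolded protein response list was called higher with 0 of 16 genes called and 5 adjusted over the list alone (adjusted p = 2e-06), and the Seminal vesicle list lower with 0 of 10 called and 6 adjusted over the list alone (adjusted p = 1.57e-05), with Hspa5 at 1.05 (SE 0.37) and Svs6 at -2.41 (SE 0.66). Seminal vesicle scores ran from 0.32 to 5.04 within the 4 early wild-type arrays, and carried-over tissue was not separated from the genotype. The Epithelial adhesion (adjusted p = 0.0282) and luminal secretory (0.0357) lists were called higher with 0 genes called. The luminal members with the largest differences, Wfdc15b at -1.30 (SE 0.59) and Spink1 at -1.23 (SE 0.79), pointed the other way. With an estimated correlation the adjusted p of all 4 lists was 0.749. With array quality as a covariate the calls of Unfolded protein response (0.499), luminal secretory (0.835) and Epithelial adhesion (0.635, with the direction turned) were lost, and that of Seminal vesicle was kept (7.55e-06). The Epithelial adhesion call was lost without B6 (0.277), S5 (0.0787), S9 (0.0552) or S11 (0.0538). The luminal call was lost without arrays of low quality (0.122) and without B6 (0.291), B11 (0.177), S5 (0.0787), S8 (0.0632), S9 (0.0505), S10 (0.0695) or S11 (0.0538). Array B6 scored -0.80 and -0.94 on these 2 lists, the lowest of the late wild-type arrays. There were 50 calls, 39 higher and 11 lower. The count ran from 6 without S5 to 198 without S1 and also moved by more than 1.5 times without B2 (25), B4 (26), B6 (81), B8 (13), B10 (9), B11 (30), B13 (33), S2 (15), S3 (14), S6 (20), S7 (23), S9 (13), S10 (30), S11 (32) or S12 (32). With 1 weight per array it was 2791, without arrays of low quality 668, and with array quality as a covariate 231, of which 26% were higher against 78%.

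OPN loss without the transgene lowered Armh3 by -0.72 (SE 0.12, adjusted p = 0.0436), the only call, while 3484 probe sets had an unadjusted p under 0.05. The Epithelial adhesion list (Epcam at -0.59 and Cldn3 at -0.59) and the Seminal vesicle list (Pate4 at -1.87 and Sva at -1.83) were called lower with 0 genes called (2 Epithelial adhesion genes adjusted over the list alone), each with an adjusted p of 0.00652 and of 0.777 with an estimated correlation. The Epithelial adhesion call was lost with array quality as a covariate (0.594) and without O14 (0.0506). Its scores were -0.81 for O14, -0.54 for O9 and -0.50 for O2, and ran from -0.09 to 0.08 on the other 5 OPN-null arrays. The AUC of the 3 late OPN-null arrays averaged 0.705. The Seminal vesicle call was lost without B11 (0.0658) or O7 (0.051). The count was 1593 without array O7, 140 without B6, 27 without O10, 3 without O8, 2 without O1 or O11 and 0 without B2, B3, B4, B8, B10, B11, B13, O2, O14 or O9. It was 2939 with 1 weight per array and 30 with quantile normalization, of which 46.7% were higher against 0%. Between the ages of wild-type prostate, limma called 0 probe sets, with 583 at an unadjusted p under 0.05. The smallest p-values were those of Cd80 (0.52), Lair1 (0.38), Tnfrsf17 (0.46), Slc16a6 (-0.87), Myom2 (-1.44) and Mmp10 (-0.44). The Skeletal muscle (adjusted p = 4.06e-08), Seminal vesicle (0.000166) and Hypoxia and glycolysis (0.0146) lists were called lower with age, each with an adjusted p of 0.734 with an estimated correlation, and with Myh8 at -2.59 (SE 1.29), Pate4 at -2.61 (SE 1.47) and Gapdh at -0.98 (SE 0.45). The Hypoxia and glycolysis call was lost with array quality as a covariate (0.281), without arrays of low quality (0.224) and without B6 (0.194), B8 (0.0913), B10 (0.0545) or B13 (0.121), and the Seminal vesicle call without B11 (0.658).

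Whether a knockout acted differently with and without the transgene was tested as an interaction, taken as the mean of early and late. Its sizes therefore describe neither age alone. Sparc differed by 0.50 (adjusted p = 0.715) in the SPARC and -0.02 (adjusted p = 0.973) in the OPN interaction. For OPN, the effect was more positive in transgenic mice for Slc25a21 by 2.92 (SE 0.27), the neuronal leucine-rich repeat gene Lrrn1 by 2.74 (SE 0.45) and Ccn3 by 2.34, and more negative for Pbsn by -2.46 (SE 0.58), Synpo2 by -2.27 and Actg2 by -2.20. The size for Slc25a21 is not exact, since it lay among the negative controls in every group but late OPN-null TRAMP (23.2% to 32% of them below it). The Neuroendocrine list (4 of 22 genes higher, 11 adjusted over the list alone) and the Smooth muscle list (5 of 12 lower, 10 adjusted over the list alone) held with an estimated correlation (adjusted p = 0.0454 for each), with Snap25 at 0.88, Syp at 0.84 and Tagln at -1.88. Calls lost with an estimated correlation were Cell cycle with 1 of 24 genes higher, Macrophages and Interferon response with 0 called (adjusted p = 0.0832 for each), Basement membrane with 0 (0.283), luminal secretory with 2 of 23 lower, Fibrillar collagen and matrix with 1 of 19 lower, Urothelium with 1 of 8 lower (0.29 for each) and Adipose tissue with 0 (0.365). Within them Defb50 was at -2.03, Top2a at 0.65, Upk1b at -1.31 and Col3a1 at -0.83. Without O7 the calls of luminal secretory (0.164), Fibrillar collagen and matrix (0.258), Basement membrane (0.252), Adipose tissue (0.134) and Urothelium (0.442) were lost, and without arrays of low quality that of Interferon response (0.0686). Fibrillar collagen and matrix was also lost without T6 (0.0515), T13 (0.0618), OT14 (0.0521), B6 (0.0652), B13 (0.0616), O9 (0.0551) or O10 (0.075), and Basement membrane without T13 (0.0667), T14 (0.0507), OT3 (0.125), OT6 (0.0645), B6 (0.0652), B11 (0.0584) or O10 (0.075). Adipose tissue was also lost without OT3 (0.058), B6 (0.0652) or B11 (0.0592), and Urothelium without T14 (0.0648), OT3 (0.0732), B6 (0.0675) or O10 (0.075). There were 311 calls, 210 higher and 101 lower. The count was 754 without array O7, 726 without OT3 and 188 without O2, and it was 1240 with 1 weight per array and 826 with array quality as a covariate, of which 52.1% were higher against 67.5%.

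For SPARC, limma called 0 probe sets in the interaction with the transgene, with 1332 at an unadjusted p under 0.05. The smallest p-values were those of Pttg1 (0.75, adjusted p = 0.162), Abi1 (0.50) and Dnajc16 (0.50) among positive and of Tcp1 (-0.58), Mrpl50 (-0.45) and Selenok (-0.45) among negative differences. The Unfolded protein response (adjusted p = 8.46e-06) and Adipose tissue (0.00468) lists were called lower and the Cell cycle (0.00324), Seminal vesicle (0.00488) and T and NK cells (0.0123) lists higher, with 0 genes called. With an estimated correlation the adjusted p was 0.454, and 0.67 for Seminal vesicle. Hspa5 differed by -1.03, Ezh2 by 0.52, Klrb1c by 0.68 and Fabp4 by -0.98. The T and NK cells call was lost with array quality as a covariate (0.184) and without B11 (0.0523), the Seminal vesicle call without ST24 (0.056), B3 (0.0512) or B11 (0.139), and the Adipose tissue call without B11 (0.066). The count was 1 without array T10 or B6, and it was 205 with 1 weight per array, 10 with array quality as a covariate and 12 without arrays of low quality. Over all 468 list tests, camera called 106, of which 25 were called with an estimated correlation and 59 by fry.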

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

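The test with array quality was set before its result was seen, though after the control probe sets had been seen, and the tests of nerve tissue, of stroma, of age and of array O12 were chosen after the results were seen. Of 90 measures in groups of 4 to 10 arrays, 6 had an array far from the others of its group, where chance gives about 1 in 20, or 4.5. In non-transgenic late prostate, array B6 had the lowest scores for the Androgen-regulated and luminal secretory list (-0.9357; others -0.03219 to 0.431), the Smooth muscle list (-0.9086; others 0.2167 to 0.4632) and the Epithelial adhesion list (-0.8027; others -0.08137 to 0.1783). Array O9 of early OPN-null non-transgenic prostate had an Epithelial adhesion score of -0.5417 (others -0.09105 to 0.07754). Array T3 of late TRAMP had a luminal secretory score of 0.4776 (others -0.2806 to 0.0185), and OT14 of early OPN-null TRAMP a quality measure of 0.7233 (others 0.7402 to 0.7452). No explanation was tested for these arrays.

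The SV40 control probe sets, which no comparison of genes used, were higher by 2.005 on transgenic than on non-transgenic arrays. The OPN effect differed between late and early tumours for 3539 probe sets and between transgenic and non-transgenic mice for 311. The test against non-transgenic mice averages both ages and uses the same late OPN-null TRAMP arrays, so these 2 results are not independent.

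The late OPN-null TRAMP pattern, with Neuroendocrine genes higher and luminal secretory and Smooth muscle genes lower, was weighed against technical explanations, of which array quality as the whole cause is argued against by 4618 calls with quality as a covariate against 4777 without it, of which 3749 were shared. Loss of smooth muscle and stroma alone is argued against by the luminal secretory list, whose mean difference was -1.54 while Neuroendocrine genes rose. The test of nerve or ganglion tissue did not decide, because the Autonomic neurons and glia list had a mean difference of 0.0405 with members moving both ways. Such tissue as the whole cause is argued against by the Cell cycle score, which added non-dividing tissue would lower. This score was 0.95 ± 0.20 (SD, n = 3) against 0.32 ± 0.09 (SD, n = 7) in late TRAMP, with ranges apart. Nerve or ganglion tissue as a part of the cause stays open. Age alone is argued against by the 7 SPARC-null TRAMP arrays of 27 to 29 weeks, whose highest Neuroendocrine score was 0.01407 against at least 0.6178 in the OPN-null tumours, 1 of them (OT6, 0.724) from a mouse of 24 weeks. Loss of OPN, a neuroendocrine tumour type in these 3 animals and an effect of age in OPN-null mice only stay open and were not tested.

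Array O12 carries a SPARC-null label and had a Sparc value of 7.238, above the highest of the 26 other SPARC-null arrays at 6.961, which is consistent with a wrong genotype label. Low array quality as the cause is argued against by its quality measure of 0.7564, within the 0.6822 to 0.799 of the other SPARC-null non-transgenic arrays. Its code belongs to the OPN-null series, and its true genotype stays open, since no named probe set measures Spp1.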

How the results depend on the processing

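The settings with array quality as a covariate and without arrays of low quality, and the list tests under each setting, were chosen after seeing the data; the others were planned. Of the named genes' values under all settings, 10323 kept direction and side of the threshold, 518 lost the call, 85 gained it and 33 turned direction, and of the list tests 2598 held, 297 lost the call and 3 turned. Except where a setting's construction shows it (fewer probe sets or arrays), the cause was not tested. The array number limits what can be detected, and 7 arrays had weak separation of positive from negative controls (AUC below 0.7).

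Counts moved by more than 1.5 times as follows, with the reported count in brackets. With the brighter 60% of probe sets: age in SPARC-null TRAMP 1 (0) and OPN in non-transgenic prostate 8 (1). With equal array medians: SPARC early 2 (4), age in SPARC-null TRAMP 1 (0) and OPN in non-transgenic prostate 0 (1). With quantile normalization: age in SPARC-null TRAMP 1 (0), SPARC in non-transgenic prostate 30 (50), OPN in non-transgenic prostate 30 (1) and OPN by transgene 551 (311). With trend and robust fitting: OPN in non-transgenic prostate 20 (1). With 1 weight per array: SPARC late 7 (2), SPARC early 1 (4), OPN early 0 (1), SPARC in non-transgenic prostate 2791 (50), OPN in non-transgenic prostate 2939 (1), transgene early 150 (8), transgene late 789 (140), SPARC by transgene 205 (0) and OPN by transgene 1240 (311). With only the groups compared: SPARC early 1 (4), OPN early 0 (1), SPARC against OPN early 1 (4), age in SPARC-null TRAMP 1 (0), OPN in non-transgenic prostate 0 (1), transgene late 68 (140) and OPN by transgene 184 (311). With only probe sets of 1 symbol: SPARC late 0 (2), SPARC early 0 (4), SPARC against OPN early 2 (4) and OPN in non-transgenic prostate 11 (1). With age in weeks as a covariate: SPARC late 72 (2), SPARC early 2 (4), OPN late 2986 (4777), SPARC against OPN early 1 (4), age in TRAMP 337 (0), age in SPARC-null TRAMP 2263 (0), age in OPN-null TRAMP 340 (4969) and OPN by age 2235 (3539). Among mice of 24 weeks SPARC late had 206 (2). With array quality as a covariate: SPARC early 29 (4), SPARC against OPN early 7 (4), SPARC in non-transgenic prostate 231 (50), transgene early 30 (8), transgene late 378 (140), SPARC by transgene 10 (0) and OPN by transgene 826 (311). Without arrays of low quality: OPN early 0 (1), SPARC in non-transgenic prostate 668 (50), OPN in non-transgenic prostate 0 (1), transgene early 60 (8), transgene late 230 (140), SPARC by transgene 12 (0) and OPN by transgene 544 (311). Of the 106 list calls, 25 held with an estimated correlation and 59 with fry, which called 70 in all.

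Leaving out each array gave these ranges: SPARC late 2 to 3, SPARC early 1 to 6, OPN late 3530 (without OT3) to 4752, OPN early 0 to 1, SPARC against OPN late 4449 (without OT3) to 6829, SPARC against OPN early 2 to 62, age in TRAMP 0 to 0, age in SPARC-null TRAMP 0 to 279, age in OPN-null TRAMP 3796 to 5138, SPARC by age 0 to 0, OPN by age 2683 to 4197, SPARC in non-transgenic prostate 6 to 198, OPN in non-transgenic prostate 0 to 1593, age in non-transgenic prostate 0 to 0, transgene early 3 to 45, transgene late 89 to 143, SPARC by transgene 0 to 1, and OPN by transgene 188 to 754.

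Directions turned in these cases, and the cause was not tested. In SPARC late, Ccnb2 was -0.02995 among mice of 24 weeks, and with array quality as a covariate Dnajb9 was -0.21 and the Unfolded protein response list had an adjusted p of 0.863. With age in weeks as a covariate, which nearly repeats the age contrasts, age in SPARC-null TRAMP gave 2.04 for Spink1 and -0.65 for Cxcl9. In OPN-null TRAMP the same covariate gave -0.2585 for Sparc, 2.76 for Pate14, 0.18 for Wfdc15b, 1.045 for Epcam, 0.12 for Dpt, 0.33 for Ly6c1, 0.23 for Gbp3 and 1.78 for Pate4, and the Seminal vesicle list had an adjusted p of 0.367. In SPARC by age, Sparc was 0.09895 with 1 weight per array, 0.08949 without arrays of low quality and 0.00942 without T3, the other end of the leave-one-out range being -0.2011 without T13. In SPARC in non-transgenic prostate with array quality as a covariate the Epithelial adhesion list had an adjusted p of 0.635. In OPN in non-transgenic prostate, Sparc was -0.004063 without B1, -0.008591 without B3, -0.1213 without O7 and -0.003052 without O9, up to 0.1304 without O2. In age in non-transgenic prostate it was 0.03986 without B1, 0.04891 without B3 and 0.07269 without B11, down to -0.19 without B6. In OPN by transgene Sparc was 0.002583 with quantile normalization, 0.005376 with 1 weight per array, 0.0293 without T3, 0.02779 without T13, 0.02409 without B1, 0.02861 without B3, 0.001434 without B10, 0.01384 without B13, 0.1413 without O7, 0.02308 without O9 and 0.001459 without O10, down to -0.1104 without O2.

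No pairing of animals by identification numbers shared between groups was detected. None of the 7 pairs in SPARC late (r from -0.0596 to 0.26) and of the 6 pairs in OPN early (r from -0.548 to 0.224) was closest to its own number. So few pairs cannot exclude a pairing. With the number as a block the counts were 3 and 0.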

Other observations

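All tests of the TC0M00000009.mm.2 probe set were chosen after the results were seen, and the random regroupings were planned. In late OPN-null TRAMP tumours Pbsn, the mouse counterpart of the rat gene whose promoter drives the transgene, differed by -5.39, while the SV40 control probe sets averaged 7.89 ± 0.53 (SD, n = 3) against 7.30 ± 0.27 (SD, n = 7) in late TRAMP. Genes outside the naming rule, chosen after their values were seen, differed in the same comparison by 0.92 for Mycn (adjusted p = 1.84e-05), -1.27 for Mycl (adjusted p = 1.11e-05), 1.16 for Cdh2 (adjusted p = 4.2e-06), -0.13 for Foxa1 (adjusted p = 0.723), -0.07 for Foxa2 (adjusted p = 0.754) and -0.50 for Sox2 (adjusted p = 0.0724). Foxa2 and Sox2 are members of the Neuroendocrine list that did not rise with it, and Cdh2 is a member of the Mesenchymal transition list.

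The securin gene Pttg1 was lower by -0.87 in SPARC-null than in wild-type non-transgenic prostate and by -0.56 in late TRAMP than in non-transgenic prostate. The unnamed TC0100001206.mm.2 averaged 7.72 in late OPN-null TRAMP, near the 7.25 to 7.53 of the SPARC-null groups, and 10.8 to 11.5 in the other groups. Its SD was 0.167 to 0.507 in the groups with low means and 0.675 to 1.97 in the others. The means of the other groups therefore do not describe their single arrays, and no cause was tested.

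TC0M00000009.mm.2 was lower in SPARC-null groups, with group means of 9.37 to 9.75 against 11.6 to 12.2. If the prefix marks the mitochondrial genome, which the annotation used here does not state, lower mitochondrial RNA as a whole is argued against by the median difference of 0.217 over the other 8 probe sets with this prefix (-0.145 to 0.390) in late SPARC-null TRAMP. Loss of SPARC itself is argued against by 2 SPARC-null arrays, S6 at 11.44 and S11 at 11.7, that lay above the lowest other array at 10.75 with Sparc at 5.73 and 6.147. The strain background of the SPARC-null line is a candidate explanation that was not tested.

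The real counts were set against random regroupings of the arrays, 100 per comparison or 84 for age in OPN-null TRAMP. The smallest share these can give is about 1 in 100, unadjusted over the comparisons, so they cannot exclude chance. The real count was far above every other regrouping for OPN late (1 as large; real 4777, highest other 449), SPARC against OPN late (1; 6563, 1230) and age in OPN-null TRAMP (1; 4969, 759). The same held for OPN by age (1; 3539, 95), SPARC in non-transgenic prostate (1; 50, 3) and transgene late (1; 140, 11). It was barely above the highest other for SPARC late (1; 2, 1) and SPARC against OPN early (1; 4, 3). For OPN by transgene (2; 311, 414) a regrouping called more probe sets than the real groups. For OPN in non-transgenic prostate 3 regroupings were as large (real 1, highest other 456), and that 1 call was lost without any 1 of 10 arrays, so it carries little weight. More regroupings were as large for SPARC early (9; 4, 6112), OPN early (6; 1, 155) and transgene early (8; 8, 2882). These counts therefore do not stand out from the regroupings, and chance stays open for them. The regroupings test counts and not single probe sets, such as TC0M00000009.mm.2 in SPARC early (limma adjusted p = 8.53e-12) and Hells in transgene early (limma adjusted p = 1.265e-06). With a real count of 0, all 100 were as large for age in TRAMP (highest other 1), age in SPARC-null TRAMP (2), SPARC by age (1496), age in non-transgenic prostate (1) and SPARC by transgene (75). Some regroupings of SPARC early, OPN early, OPN in non-transgenic prostate and transgene early called several times the real count. Regroupings of SPARC by age and SPARC by transgene called up to 1496 and 75. Whether a structure of the samples other than the groups lies behind these counts was not tested.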
